A study of Mus musculus with 7 samples.

How the data were processed

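Hippocampal neurons were prepared from C57BL/6J mouse embryos at embryonic day 18.5 and cultured for 11 days, per the labels. The cultures were then treated with 55 mM KCl, which depolarises neurons, for 4 h, or left untreated. DNA fragments carrying 5-methylcytosine (5mC) were enriched with an antibody and sequenced (MeDIP-seq). There were 3 untreated and 3 KCl libraries, and 1 pooled input library, which was not analysed here. Nothing in the labels says whether the 3 libraries of a group came from separate cultures or animals. The p-values for single regions and for values per library thus measure the spread between these libraries, which may be technical. Those for the share of genes with a region take genes or gene ends as units, pool the 6 libraries and do not measure that spread.

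A service company built the libraries and analysed the reads, per the labels' protocols. The aligner BWA, the region caller SICER and the genome build mm10 are named in the submitters' processing notes, without versions. Read filters, fragment extension, caller settings and read totals are not given in the sources used here, so the depth per library is unknown and no counting interval is given. The deposited values came as 13 tracks, per the file headers. For each library 1 track gave the called intervals and 1 track gave a summit position and height for each interval, and 1 further track gave the active regions of all libraries together. Heights deposited by the authors were whole numbers of at least 6 and behave like a pileup of fragments. Whether they were scaled between libraries is not stated. Of the 133337 active regions, 133311 (99.98%) matched exactly a merge of touching or overlapping intervals of the 6 libraries, so intervals were called per library and then merged. Each active region took, per library, the height of its highest summit, and a region with no interval in a library had no value there.

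The named test for signal values, fixed before the data were examined, was used because the file holds peak heights and no read counts. Heights of the 27310 regions called in all 6 libraries were taken as log2(height + 1). Regions with a mean height at or above the 25th percentile (18.7) were kept, which left 20537. The comparison used limma 3.58.1 in R 4.3.3 with an intensity trend in the variance and Benjamini-Hochberg adjustment over regions, at an adjusted p threshold of 0.05, two-sided. Fold changes are on the log2(height + 1) scale and understate changes of low regions. The median change over tested regions was -0.25, and 90.6% of them were lower with KCl. This shift rests largely on single libraries, as it was -0.02 without KCl replicate 3 and -0.46 without KCl replicate 1. Changes of single regions are therefore given relative to the median and called relative log2 changes. Their SEs come from the same fit after median centring, and p-values are those of heights as deposited unless centring is named. On simulated heights with 200 changed regions, 86.7% of regions changed by 2-fold were recovered after median centring and 8.52% without it, counted among those that passed the filter, with 0 to 8 false calls. At 1.5-fold these shares were 17.2% and 0%, and at 4-fold both were 100%. The changed regions were drawn from the higher part of the height range. Every simulated region had the same spread beyond counting, and no loss of calls was simulated. The shares may therefore overstate recovery in the data.

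Samples with the same replicate number in both groups were checked for pairing. Their deviations from the group means correlated across regions at 0.11 in each of the 3 pairs, while the correlations between different numbers lay between -0.09 and -0.01. By the limit of 0.1 fixed for this check the numbers pair the samples, although the labels do not say what a number marks. Deviations cancel within a group, so positive correlations for the same number bring negative ones for different numbers by construction. The main tests do not use the pairing. A replicate block, which compares libraries within a number, was run as an alternative for regions, lists and mean height.

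Gene positions came from the RefSeq annotation of GRCm38.p6, whose chromosome coordinates are those of mm10. The table used holds gene starts and ends without strand or exons, so promoters, exons and introns were not assigned. Windows of 1 kb around both gene ends replaced the planned windows around transcription start sites. All 465 gene names of 21 lists fixed before the data were examined were matched. Coordinates are 1-based.

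List members with a region at a gene end were compared with all other protein-coding genes by two-sided Fisher's exact tests, adjusted over the 21 lists (scipy 1.17.1). As a check added after the data were examined, the share was set against 10000 draws of protein-coding genes matched on length in 20 bins. Changes with KCl over the regions of a list (gene ends or gene body, at least 3 tested regions) were tested with camera at a preset correlation of 0.01 and with fry. Values per library were compared by two-sided exact permutation tests, for which 3 against 3 libraries give a smallest p of 0.1. Overlap between libraries was the Jaccard index of their intervals with at least 1 bp shared.

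Named regions followed a rule fixed before the data were examined. It takes, per direction, the 10 largest changes past the threshold with all 3 KCl values on the same side of the untreated values, or, where fewer than 5 pass, the 5 with the lowest p in that direction. It adds the members of each list with a passing gene-end region, else up to 4 members with the lowest p, and always Gadd45a, Gadd45b, Gadd45g, Bdnf, Fos, Npas4, Arc, Egr1 and Nr4a1. Because p came from heights as deposited, the shift favoured lower members in these rankings. Other genes are named as examples chosen after their values were seen, and are marked so.

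Alternatives fixed beforehand were quantile normalization, median centring, a replicate block, leaving out each library, no variance trend, no filter, pseudocounts of 0.1 and 10, regions of at least 500 bp, autosomes only, an adjusted p under 0.1, an estimated correlation for camera, other gene-end windows (500 bp and 2 kb), and stricter region sets and overlaps.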

Results

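5mC enrichment was mapped in cultured mouse hippocampal neurons, untreated or depolarised with 55 mM KCl for 4 h, to find DNA methylation targets of neuronal activity. The untreated libraries held 87151, 87302 and 72947 called intervals, and the KCl libraries 93470, 60949 and 34834. The mean was 82467 ± 8245 intervals without KCl and 63084 ± 29376 with it (SD, n = 3 each; exact permutation p = 0.4, two-sided, smallest possible 0.1). Intervals covered 24.0 to 30.1 Mb in the untreated libraries and 11.3 to 32.1 Mb in the KCl libraries. The number of intervals thus differed more within the KCl group than between the group means.

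**Figure D1:**
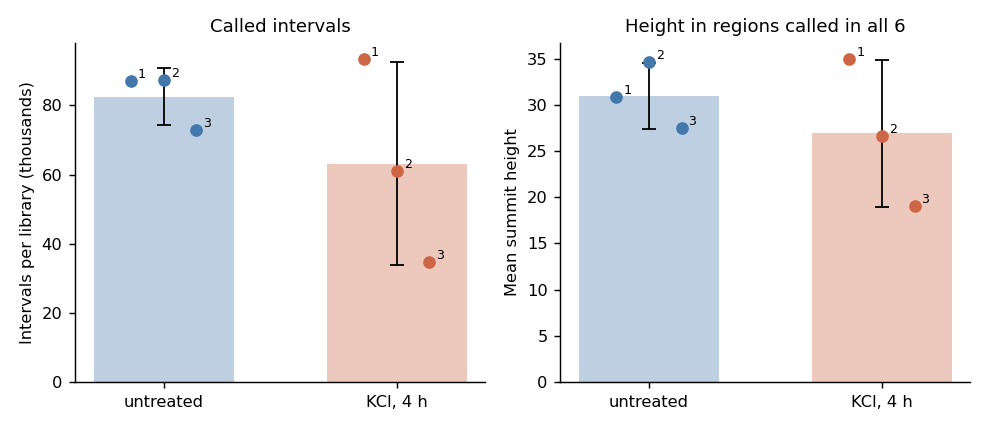
Called intervals per library, in units of 1000 (left), and mean summit height over the 27310 regions called in all 6 libraries (right) for untreated and KCl-treated neurons. Bars are means of 3 libraries, error bars are SD, points are libraries with their replicate number, and KCl replicate 3 is the lowest point in both panels.

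The same regions were enriched with and without KCl to about the degree that replicates shared them. Over the 15 pairs of libraries the Jaccard overlap averaged 0.504 ± 0.0907 (SD), from 0.344 to 0.602. It was 0.506 within groups and 0.503 between groups, and 4 of the 10 ways of splitting the 6 libraries gave a difference as large. Without KCl replicate 1 it was 0.542 within and 0.462 between groups, with 1 of 10 splits as large. Without any other single library the difference ranged from -0.0338 to 0.0298. Of the 133337 active regions, 27310 (20.5%) were called in all 6 libraries and 39085 (29.3%) in a single library. Median height was 24 in regions called in all 6 and 11 in regions called in 1. There were 1349 regions called in every untreated and no KCl library, and 49 the other way round. The ratio of 27.5 was 1.10 when each library kept its 34834 highest intervals, with 257 and 233 such regions. Without KCl replicate 3 the ratio was 1.36, without KCl replicate 2 it was 10.3, without untreated replicate 2 it was 15.0, and without KCl replicate 1 it was 76.7.

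Heights in the shared regions did not separate the groups. The mean height over regions called in all 6 libraries was 31.0 ± 3.56 untreated and 26.9 ± 7.96 with KCl (SD, n = 3 each), a difference of -4.08 (exact permutation p = 0.5). Without KCl replicate 3 the difference was -0.164, without KCl replicate 1 it was -8.06, and without untreated replicate 2 it was -2.24.

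Region by region, no change in 5mC enrichment with KCl passed the threshold among regions called in all 6 libraries. KCl replicate 3 called 25.7% of the active regions, and a region that lost its call in any library was outside this test. Of 20537 regions tested with limma, 0 were higher and 0 lower at an adjusted p under 0.05, and the lowest adjusted p was 0.932. At an unadjusted p under 0.05 there were 0 higher and 231 lower regions as deposited, and 405 higher and 342 lower after median centring. With no change at all, a share of about 0.05 of the 20537 regions would reach this p by chance. Higher and lower regions added up to less than that share, as deposited and after centring. The number lower as deposited followed single libraries, with 4325 without KCl replicate 1 (lowest adjusted p = 0.0842), 186 without KCl replicate 3, and 43 and 40 without untreated replicates 1 and 2. Of these counts, only the 4325, out of 20796 regions tested, exceeded that share, on heights that carry the shift. After centring there were 860 higher and 444 lower of 31004 tested without KCl replicate 3. There were 537 and 224 of 21891 without KCl replicate 2, and these counts also stayed below that share. Without KCl replicate 1 there were 507 and 566 of 20796 after centring, slightly above it. The 5 regions with the lowest p in each direction are given here although they did not pass. The leading higher region lay in Hs6st3, a heparan sulfate 6-O-sulfotransferase gene, at chromosome 14, 119798763 to 119799094 (mm10). Its height was 17.0 ± 1.00 untreated and 28.3 ± 5.69 with KCl (SD, n = 3), a relative log2 change of 0.93 (limma SE 0.22; adjusted p = 0.932 as deposited and 1.00 centred), with all 3 KCl heights above all 3 untreated heights. The next were in Stard13 (chromosome 5, 151039327 to 151039837, relative log2 change 0.84) and in Denn2b (chromosome 7, 109655460 to 109655975, 0.81). Them7 (chromosome 2, 105302250 to 105302689, 0.80) and the predicted gene Gm11349 (chromosome 13, 25582966 to 25583516, 0.79) followed.

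The leading lower region was intergenic, 72045 bp from Pld5, at chromosome 1, 176353557 to 176354021. Its height was 30.0 ± 3.00 untreated and 14.0 ± 7 with KCl, a relative log2 change of -0.89 (limma SE 0.24; adjusted p = 0.932 as deposited and 1.00 centred). Regions in Lekr1 (chromosome 3, 65831192 to 65831578, relative log2 change -0.83), Sash1 (chromosome 10, 8818372 to 8819081, -0.74) and the receptor tyrosine kinase gene Alk (chromosome 17, 72244351 to 72244643, -0.72) came next. The fifth lay 13451 bp from Tiam1, which encodes an activator of the small GTPase Rac (chromosome 16, 89772762 to 89773660, -0.74). Limma SEs of these 10 changes were 0.21 to 0.25. With centring and a replicate block together, limma gave its lowest adjusted p among them at Hs6st3 (0.461), Lekr1 (0.531) and near Pld5 (0.592). Without single libraries the change at Stard13 ranged from 0.55 to 1.14, and the other 9 stayed within 1.5 times. These fits reuse the libraries by which the regions were chosen, so they are no independent support.

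Among genes that neurons induce on depolarisation, several had no enriched region, and no tested region of the others passed. Fos and Arc, classic immediate early genes, had no region in the gene body or within 1 kb of either end, and neither did Gadd45b and Gadd45g, members of the stress-induced family linked to DNA demethylation. Gadd45a had a single region next to the gene (chromosome 6, 67034315 to 67034983), called in 2 untreated libraries and 1 KCl library at a mean height of 11. Bdnf, which encodes brain-derived neurotrophic factor, had a region in its gene body (chromosome 2, 109723371 to 109724128) with a height of 25 ± 7 untreated and 27.0 ± 14.2 with KCl (SD, n = 3), a relative log2 change of 0.22. The gene-body regions of the transcription factor genes Egr1 (chromosome 18, 34862827 to 34863861), Npas4 (chromosome 19, 4988079 to 4988688) and Nr4a1 (chromosome 15, 101270013 to 101271092) had relative log2 changes of 0.02, -0.24 and -0.05. Limma SEs of these 4 changes were 0.17 to 0.24, and adjusted p was 0.932 or above as deposited and 1.00 centred. Further regions were not called in all 6 libraries and not tested. At Nr4a1 these were a region in 2 KCl and 0 untreated libraries (chromosome 15, 101258433 to 101258695) and a region in 3 untreated and 2 KCl libraries (101273890 to 101274272). Npas4 had a further region in 1 untreated library, and the Gadd45a region was likewise not tested. The Egr1 and Nr4a1 values turned in sign when single libraries were left out, and the others ranged over 0.0145 to 0.52 for Bdnf and -0.39 to -0.0763 for Npas4.

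The 24 immediate early genes had 9 tested regions, of which 3 were higher and 6 lower than the median region. The members with the lowest p were Nr4a2 (relative log2 change -0.41), Fosl2 (-0.33), Csrnp1 (-0.29) and Npas4. The late activity response genes had 7 tested regions, 3 higher and 4 lower, led by Plk3 (-0.24, in a region shared with Tctex1d4), the postsynaptic scaffold gene Homer1 (-0.13), Sik1 (-0.11) and Gpr3 (-0.05). Genes of TGF-β signalling had 24, 13 higher and 11 lower, led by the inhibitory Smad gene Smad7 (-0.31), Tgfb1 (-0.29, in a region shared with B9d2), Smad1 (-0.19) and Tgfbr2 (-0.17). The DNA methylation machinery had 16, 11 higher and 5 lower, led by the methyltransferase genes Dnmt3a (-0.33) and Dnmt1 (-0.31) and the dioxygenase genes Tet3 (-0.29) and Tet1 (-0.19). Limma SEs of these changes were 0.13 to 0.24. Without single libraries the changes ranged over -0.52 to -0.24 for Nr4a2, -0.49 to -0.15 for Fosl2, -0.38 to -0.14 for Csrnp1, -0.47 to -0.0715 for Plk3, -0.26 to -0.00971 for Homer1, -0.23 to -0.0488 for Sik1 and -0.27 to -0.12 for Tgfbr2. For the methylation machinery they ranged over -0.50 to -0.21 for Dnmt3a, -0.53 to -0.10 for Dnmt1 and -0.28 to -0.11 for Tet1, and Gpr3 and Smad1 turned in sign. In each of these lists 0 regions passed, adjusted over the list alone or over all regions. Camera gave adjusted p = 0.831 for the immediate early genes and 0.931 for the other 3 lists.

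A single list passed camera, and 0 lists passed fry, the second test fixed for the lists. Regions in stress and glucocorticoid axis genes lay above the median region in 12 of 15 cases, with a median relative log2 change of 0.18 (adjusted p = 0.0395). With an estimated correlation the list had adjusted p = 0.986, after median centring 0.0577, without a filter 0.158, and with regions of at least 500 bp 0.0626. These regions belonged to 8 genes. The mineralocorticoid receptor gene Nr3c2 had 3, with a median relative log2 change of 0.36, and the glucocorticoid-induced kinase gene Sgk1 had 3, with 0.28. The members with the lowest p were Crhr2 (-0.25, chromosome 6, 55128728 to 55129167), Fkbp5 (-0.18, chromosome 17, 28432120 to 28432718), Nr3c2 (0.55, chromosome 8, 77235087 to 77235500) and Ntrk2 (-0.04, chromosome 13, 59021565 to 59022135). Without single libraries these changes ranged over -0.45 to -0.022 for Crhr2, -0.33 to -0.0319 for Fkbp5 and 0.28 to 0.72 for Nr3c2, and Ntrk2 turned in sign. The other tested region lay at 0.45 for Fkbp5, 0.026 for Crhr2 and 0.050 for Ntrk2. Median relative log2 changes of these genes were 0.14, -0.11 and 0.0066 in the same order, so the regions shown do not stand for their genes. Of the 15 regions, 0 passed, adjusted over the list alone (lowest adjusted p = 0.935) or over all regions. The call held without untreated replicate 3 (adjusted p = 0.0192) and ended without any of the other libraries (0.0557 to 0.465). Fry, which asks whether a list moves by itself, gave adjusted p = 0.741 with a downward direction on heights as deposited and 0.147 with an upward direction after centring.

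The other 17 lists tested had camera adjusted p between 0.831 and 0.931, and in each of them 0 regions passed, adjusted over the list alone. Their members with the lowest p included Grik1, Grm8, Grm2 and Grin2a for glutamate receptors, Gabrg3, Gabbr2, Gabrb2 and Gabra2 for GABA receptors, and Camk2d, Cacna1d, Cacng2 and Camk4 for calcium signalling. They included Pcdhb3, Pcdhb20, Pcdhb7 and Pcdha1 for clustered protocadherins, and Runx1, Nkx2-5 and Gata2 for regulators of non-neural lineages. Among markers of cell types they included Prox1, Rbfox3, Bcl11b and Dlg4 for neurons, Glul, Aldh1l1 and Apoe for astrocytes, and Cspg4, Mbp, Mobp and Myrf for oligodendrocytes. They included Cx3cr1, Itgam and C1qb for microglia, Col1a1, Pecam1, Flt1 and Kdr for endothelial and mesenchymal cells, and Ttn, Myh6, Umod and Myh7 for non-neural tissues. Of 54 tested regions of imprinted genes, 27 were higher and 27 lower than the median region, and of 30 of germline genes 9 and 21. Imprinted genes were led by Grb10 (relative log2 change -0.36), Nnat (-0.28, in a region shared with Blcap), Peg3 (-0.27) and Gnas (-0.27), and germline genes by Tuba3b (-0.23), Tdrd1 (-0.20), Sohlh2 (-0.16) and Sycp3 (-0.15), with limma SEs of 0.16 to 0.23. Without single libraries they ranged over -0.46 to -0.22 for Grb10, -0.41 to -0.13 for Gnas, -0.38 to -0.0999 for Peg3, -0.37 to -0.11 for Tuba3b, -0.33 to -0.12 for Tdrd1, -0.34 to -0.0214 for Sohlh2 and -0.27 to -0.0411 for Sycp3. The Gadd45 family, housekeeping genes and Hox genes had fewer than 3 tested regions each, with Polr2a and Hoxa9 the tested members of the latter 2 lists.

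Where the enriched regions lay differed strongly between gene groups in both conditions. Lists, features and chromosomes were not matched on CpG density (CpG sites per length). Differences in CpG density and in methylation are therefore not told apart here. Of 21887 protein-coding genes, 5680 (26.0%) had a region within 1 kb of a gene end, and 13807 (63.1%) had one in the gene body. The germline list was fixed beforehand as genes whose promoters are methylated in somatic cells. A high share was therefore foreseen for it and says little about germline genes in general. These genes had a region at an end in 25 of 30 cases (83.3%, odds ratio 14.3, Fisher's exact adjusted p = 1.56e-09). Imprinted protein-coding genes, expressed from the maternal or the paternal copy, had one in 18 of 25 cases (72%, odds ratio 7.36, adjusted p = 1.98e-05). In a check chosen after the data were seen, random genes matched on length had one in 27.6% and 26.6% of cases for these lists (adjusted p = 0.0021 for both, from the smallest p the draws can give, 0.0002). The imprinted list too was fixed beforehand for a property tied to methylation, so its high share says little about other genes. Per library, the share of germline genes was 80% ± 3.33 untreated and 74.4% ± 3.85 with KCl (SD, n = 3 each; exact permutation p = 0.3), and that of imprinted genes 68.0% ± 4.00 and 61.3% ± 8.33 (exact permutation p = 0.5). Protein-coding genes outside the germline list had shares of 18.7%, 19.4% and 15.7% in untreated replicates 1 to 3. In KCl replicates 1 to 3 these were 19.7%, 14.5% and 9.23%, so lower shares with KCl were not particular to these lists.

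The germline list included some of the highest gene-end regions of the lists, here chosen after their values were seen. The region at Dazl, which encodes an RNA-binding protein of germ cells, had a height of 153 ± 33.0 untreated and 133 ± 38.5 with KCl (SD, n = 3; chromosome 17, 50293063 to 50294077). At Hormad1, a gene of meiotic chromosomes, the heights were 106 ± 25.8 and 89.7 ± 27.9 (chromosome 3, 95559349 to 95560090), and at Sycp1, of the synaptonemal complex, 91.7 ± 10.4 and 75.3 ± 16.6 (chromosome 3, 102935272 to 102936422). Among imprinted genes the gene-end region of Gnas had heights of 96.7 ± 10.0 and 81.3 ± 26.6 (chromosome 2, 174284511 to 174285639), Cdkn1c, a cell-cycle inhibitor gene, 90.7 ± 17.0 and 72.7 ± 21.8 (chromosome 7, 143459425 to 143461657), and Plagl1 84.3 ± 15.0 and 77.3 ± 26.6 (chromosome 10, 13090459 to 13091298). The relative log2 changes of these 6 regions were between -0.10 and 0.08, each smaller than its limma SE (0.09 to 0.12).

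**Figure D2:**
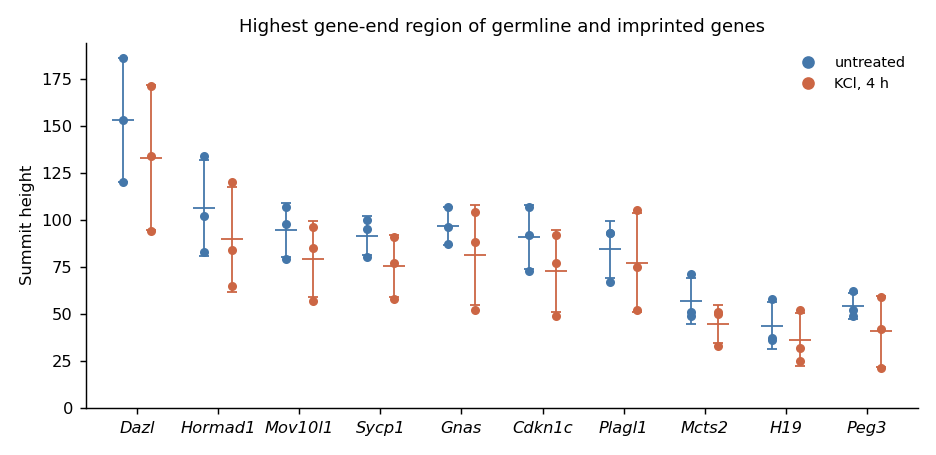
Summit height of the highest gene-end region of 4 germline and 6 imprinted genes, per library (points), with mean and SD of 3 untreated and 3 KCl libraries. The groups overlap at every gene shown, and Dazl is the highest at 153 ± 33.0 and 133 ± 38.5.

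Clustered protocadherins, neuronal cell-surface genes in tandem arrays, had a region at an end in 26 of 57 protein-coding cases (45.6%, odds ratio 2.40, adjusted p = 0.00914). Of these, 14 genes shared 1 region at the common end of the α cluster (chromosome 18, 37187838 to 37188356), called in 5 libraries and absent from untreated replicate 2. Counted by distinct gene ends, 20 of 87 (23.0%) had a region against 14.6% of other ends (adjusted p = 0.205), and with regions called in all 6 libraries 6 of 57 genes had one (adjusted p = 0.946).

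The other 18 lists did not pass, with adjusted p from 0.107 to 1. Counts were 10 of 20 for regulators of non-neural lineages (adjusted p = 0.107, and 0.0162 with windows of 500 bp), 13 of 30 for TGF-β signalling, 9 of 24 for late activity response genes and 6 of 15 for stress axis genes. They were 4 of 24 for immediate early genes, 4 of 20 for the DNA methylation machinery, 1 of 3 for the Gadd45 family, 6 of 21 for glutamate receptors, 3 of 17 for GABA receptors and 5 of 25 for calcium signalling. Markers of neurons had 8 of 20, of astrocytes 4 of 12, of oligodendrocytes 6 of 12, of microglia 5 of 13, of endothelial and mesenchymal cells 3 of 14, and of non-neural tissues 7 of 18. The lowest shares were those of Hox genes, 6 of 39, and housekeeping genes, 2 of 20 (Hprt and Polr2a).

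**Figure D3:**
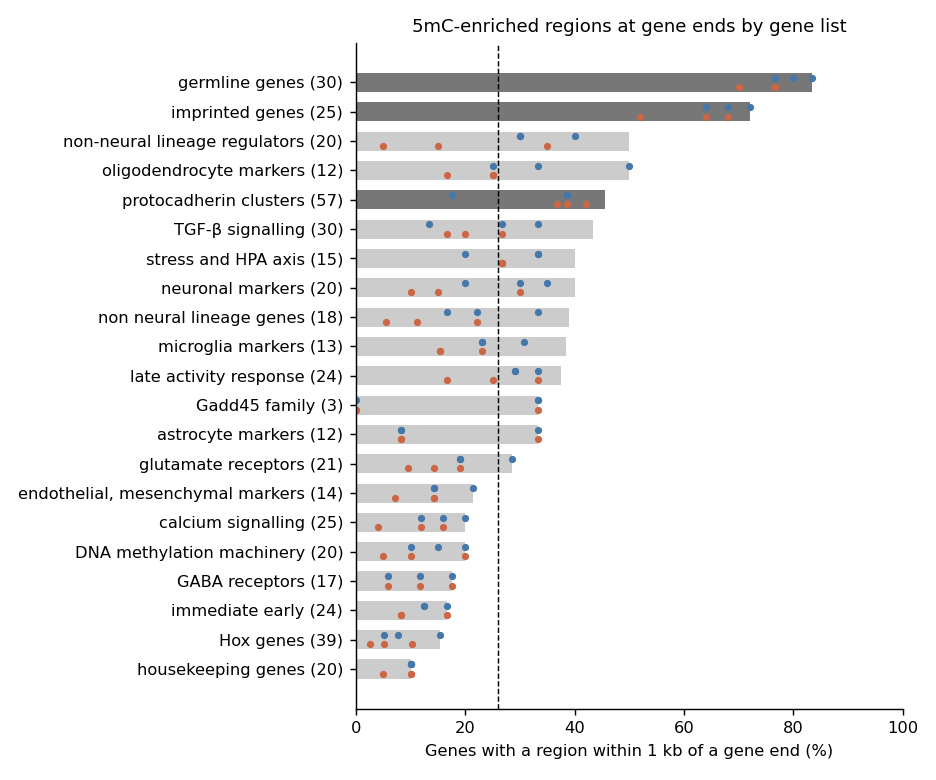
Share of the genes of each list with an enriched region within 1 kb of a gene end, in percent, over all libraries (bars, number of protein-coding genes in brackets) and per library (blue points untreated, orange points KCl). Dark bars passed Fisher's exact test at an adjusted p under 0.05, the dashed line marks other protein-coding genes at 26.0%, and germline genes are highest at 83.3%.

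Genome features were taken from protein-coding genes, so sequence that lies only in other genes counts as outside. By these features, 50.3% of the bases in active regions lay in gene bodies, 4.30% within 1 kb of a gene end and 45.4% outside both. These features made up 36.6%, 2.93% and 60.5% of the span between the first and last gene of each chromosome. Per library the shares were 51.8% ± 1.12, 4.65% ± 0.249 and 43.5% ± 1.36 (SD, n = 6), and untreated and KCl libraries did not separate (exact permutation p = 0.4 for each). Among long genes, Wwox, a tumour suppressor gene, held 45 regions called in all 6 libraries and Camta1, which encodes a calmodulin-binding transcription activator, 42. Among genes of at least 20 kb the highest density was at Pax6, a regulator of neural and eye development, with 19 regions in 29.5 kb. These 3 were chosen after their values were seen.

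Autosomes held 42.5 to 66.3 active regions per Mb, the X chromosome 13.9 and the Y chromosome 0.991. X regions per Mb were 0.258 of the autosomal value (mean of the 6 libraries 0.243, SD 0.0237). The X share of regions was 1.68% ± 0.165 untreated and 1.66% ± 0.191 with KCl (SD, n = 3 each; exact permutation p = 0.8).

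**Figure D4:**
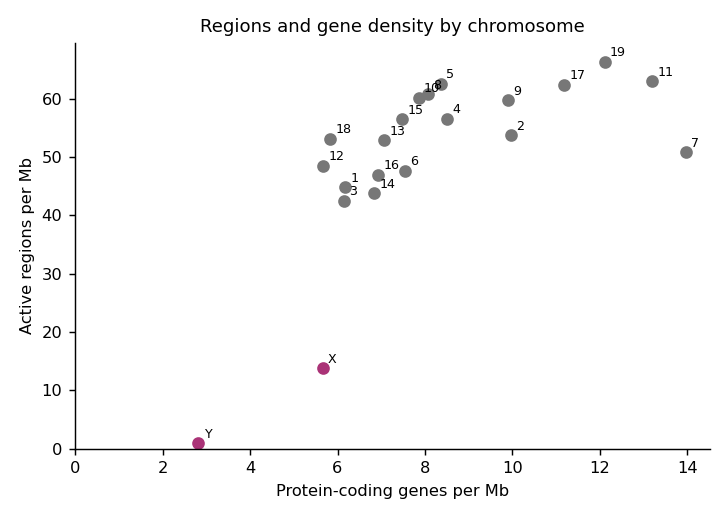
Active regions per Mb against protein-coding genes per Mb for each chromosome (grey autosomes, purple X and Y). X lies at 13.9 regions per Mb, below all autosomes, which lie between 42.5 and 66.3.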

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

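Settings named as added, all leave-one-out values except those of the tests of regions and gene lists, and all values from regions called in all 6 libraries, gene bodies, distinct gene ends, length-matched genes and equal numbers of intervals, and the ratio of regions called in a single group, were chosen after seeing the data. The count of 0 changed regions held under quantile normalization, median centring, the replicate block, no trend, no filter, both pseudocounts, regions of at least 500 bp, autosomes, an adjusted p under 0.1 and without each library (0 to 0), although the lowest adjusted p ranged from 0.0842 without KCl replicate 1 to 1.00. It also held with the replicate block and median centring together and with absent calls left missing (0 each, added). With absent calls set to the lowest height (added), 11 regions passed, 6 higher and 5 lower. Each lacks a call in at least 1 library. They include Sfi1, Tmem267 and the start of chromosome 9, near some of the highest regions; the cause was not tested.

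The count of 1 list past camera was 1 with the replicate block and with gene-body regions. It was 0 with quantile normalization, median centring, an estimated correlation and gene-end regions, and 0 to 1 without single libraries. It was 0 with median centring and the block (adjusted p = 0.0511) and with centring and an estimated correlation (adjusted p = 0.623, both added). It was 0 with fry, fixed beforehand beside camera, on heights as deposited or centred. By itself the replicate block changed no call in the tests of regions, lists and mean height, where it was run. The cause was not tested.

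The difference in mean height stayed negative, at -4 for medians, -4.08 with the replicate block (exact p = 0.5) and -8.06 to -0.164 without single libraries. Jaccard overlap stayed within its SD, 0.490 to 0.562 without single libraries. The difference between overlap within and between groups was -0.00400 with equal numbers of intervals and ranged from -0.0338 to 0.0802 without single libraries, so its direction was not fixed. The ratio of regions called only in untreated libraries to the reverse was 1.10 with equal numbers of intervals and 1.36 to 76.7 without single libraries.

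Germline and imprinted genes kept their enrichment in each alternative. The number of lists past the threshold was 3 or 2 in all alternatives except gene bodies, where it was 9, and 4 against length-matched genes, with clustered genes counted singly. With windows of 500 bp lineage regulators passed and protocadherins did not. With 50% of a window covered, the odds ratios of protocadherins, lineage regulators and TGF-β genes were 0 and that of Hox genes 4.43. With regions called in all 6 libraries that of lineage regulators was 0.625.

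The share of bases in gene bodies was 51.8% for regions at or above the median height, 51.9% and 47.3% with windows of 500 bp and 2 kb, 49.1% by midpoints and 54.1% for regions called in all 6 libraries. Gene ends held 4.61%, 2.15%, 8.42%, 3.94% and 5.25% in the same order. Between genes lay 43.6% for regions at or above the median height, 46.9% by midpoints and 40.7% for regions called in all 6 libraries. The X ratio to autosomes was 0.224 for regions at or above the median height. The windows set the values they name by construction; the cause of the other moves was not tested.

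Of 41 regions named with a change, 36 kept their sign in every setting and 0 passed in any. Of these 36, 23 moved by over 1.5 times without single libraries and 13 by less. In these fits Gpr3 ranged from -0.34 to 0.10, Smad1 from -0.46 to 0.00144, Ntrk2 from -0.11 to 0.0627, Egr1 from -0.0346 to 0.0904 and Nr4a1 from -0.18 to 0.19. With absent calls at the lowest height Ntrk2 was at 0.000515, and with absent calls left missing Egr1 was at -0.00984; the cause was not tested.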

Other observations

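All tests in this part were chosen after the results were seen. Among genes that the comparisons did not single out, Hox genes, which set position along the body axis, had few regions in their gene bodies. A region lay in 7 of 39 Hox genes (17.9%), against 40.6% of length-matched protein-coding genes (adjusted p = 0.0137 over 21 lists, permutation draws). Hox genes lie in clusters and are not independent of each other. Hoxa9 was the only member with regions called in all 6 libraries. Housekeeping genes had a region in 6 of 20 cases (30%) against 52.8% of matched genes, which did not pass (adjusted p = 0.198). All 21 glutamate receptor genes and all 17 GABA receptor and synthesis genes had a gene-body region, but matched genes had one in 93.5% and 90.3% of cases (adjusted p = 0.703 for both). Imprinted genes (96% against 69.0%) and germline genes (93.3% against 66.9%) each passed at adjusted p = 0.0042. Both lists were fixed for a property tied to methylation, so these shares too say little about other genes. Clustered protocadherins (96.5% against 70.1%) had the same adjusted p, but their genes overlap and share regions, so the test counts them as more independent than they are.

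Of the 10 highest regions, 8 lay outside protein-coding genes. The highest, with heights from 280 to 421, overlapped the ribosomal RNA sequence AY036118 at chromosome 17, 39842872 to 39848870. Others lay on chromosome 2 (98662171 to 98663055, mean height 270) and at the start of chromosome 9 (3025005 to 3027886, mean height 192), with the nearest protein-coding genes 1030499 and 307345 bp away. The input library was not analysed here, so these heights are not corrected for copy number.

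More regions were called in every untreated and in no KCl library than the reverse, by a ratio of 27.5. A candidate explanation is the number of intervals called per library, which was lowest in KCl replicates 2 and 3. With the same number of intervals kept per library the ratio was 1.10, and a split that put untreated replicates 1 and 2 with KCl replicate 1 gave a ratio of 147 on all intervals. Fewer methylated regions after KCl stay possible, since a loss over the whole genome could itself lower the number of intervals. The exact permutation p of that number was 0.4, and 3 against 3 libraries cannot go below 0.1, so this and the number of intervals cannot be told apart.

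The X chromosome held 13.9 regions per Mb against 42.5 or more on each autosome. Its low gene density, 5.66 protein-coding genes per Mb, does not account for this, since the 4 autosomes closest in gene density, chromosomes 1, 3, 12 and 18, held at least 42.5 regions per Mb. X copy number, with the sex of the embryos not given in the sources used here, CpG density and repeats that hinder alignment were not tested. No biological explanation was tested, because the design names none.

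For the counts of regions and lists that passed with KCl, the 6 libraries allow 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 0 regions and the highest other split 29. Any split gives at least 0, so counting splits says nothing about this result. The split with 29 set untreated replicates 1 and 2 and KCl replicate 1, the libraries with the most intervals, against the rest, which points to the scale of the libraries, and after median centring it gave 0. It parts a single pair of replicate numbers. Among the 4 splits that part all 3 pairs, the highest other gave 0. For lists the real split gave 1 and the highest other 0, so 1 of 10 splits gave as many.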
